A study of Homo sapiens with 57 samples.

How the data were processed

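Gene expression was measured by RNA-seq of total RNA in 57 libraries from 4 human breast cancer cell lines, named in the labels MB231, BT549, MCF7 and MCF7PR. The libraries fall into 19 groups of 3. In the 48 libraries labelled May, each line had 12, 3 each for DMSO (vehicle), MYTi (30 nM of the PKMYT1 inhibitor RP-6306), ATRi (10 nM of the ATR inhibitor RP-3500) and COMB (both), applied for 48 h. The other 3 groups are vehicle libraries of BT549 labelled Jan and of MCF7 and MCF7PR labelled Apr.

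Per the labels, the authors checked reads with FastQC 0.11.9, trimmed them with cutadapt 4.1, aligned them to GRCh38 with STAR 2.7.10b and counted them per gene with featureCounts of Subread 2.0.6 on GENCODE 29. The deposited values are raw fragment counts per gene, not split by strand and not normalised. Whole numbers and library totals of 15937770 to 42213423 (median 19613817) were found in the deposited count tables. All 58721 gene identifiers and their coordinates matched the GENCODE 29 annotation. Current gene symbols were used, which differ from those of that annotation at 21726 genes. Because strands were not separated, counts of genes that overlap another gene, or that have close paralogs, are uncertain. No duplicate libraries were found within groups: among 57 pairs of replicate libraries, 0 had identical counts, and the chi-square per gene was 6.48 to 211, so the spread exceeded counting error in each pair. Libraries of different groups were not compared in this way.

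Counts were analysed in R 4.3.3 with edgeR 4.0.16 (trimmed mean of M values scaling, filterByExpr by group, quasi-likelihood test) and limma 3.58.1, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Adjusted p-values are Benjamini-Hochberg over all genes tested in a contrast, with a threshold of 0.05. Levels are in CPM (counts scaled to a common library total), given as mean ± SD, and changes are log2 ± SE. The 12 May libraries of a line shared 1 estimate of the spread. MCF7PR was compared with MCF7 over their 12 vehicle libraries with month as a term, and BT549 with MB231 over 6. Differences between 2 lines in the COMB response were tested as an interaction over 24 libraries. These tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated otherwise.

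The planned fit has no term for the replicate number. The labels give the 4 treatments of a number in a line the same experiment tag, and libraries of the same number correlated in most but not all cases. After subtraction of group means, libraries of the same number correlated across genes with a median of 0.44 in MB231, 0.31 in BT549, 0.30 in MCF7 and 0.66 in MCF7PR. Libraries of different numbers had medians of -0.15, -0.10, -0.16 and -0.27. Because group means were subtracted, these negative values follow from the positive ones and add no separate evidence of pairing. In BT549 vehicle and COMB of the same number gave only 0.149, -0.067 and 0.177, with 0.134 for vehicle 1 and COMB 2, and MCF7 COMB 1 gave 0.018 to 0.105. Genes are not independent replicates in these correlations. Between lines the same number gave medians of only 0.02 to 0.08. The fit with the replicate number as a block, also fixed beforehand as an alternative, is called the paired fit here and is given beside the planned, unpaired one. In the report, a drug-treated gene "rose" or "fell" where it passed the threshold in the paired fit, unless the unpaired fit is named.

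The naming rule covered COMB against DMSO, both line comparisons and both differences. It took the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 1. No overlap between the groups was also required, except for the differences. It also took the 2 members of each list with the smallest p, and 10 genes in every case: RB1, PKMYT1, ATR, WEE1, CHEK1, CCNE1, CDK1, E2F1, CDKN1A and MKI67. For other contrasts it took 3 rises and 3 falls. Applying the same rule to the paired fit, with movement in the same direction in all 3 pairs in place of no overlap, was chosen after seeing the data. That movement was not required of the differences either. The paired form gave most of the genes named below. RPS6KB1, MED4 and EBPL, and CDKN2A in MCF7PR, were named after their values were seen.

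The 16 gene lists cover E2F targets, G2 and mitosis, replication-dependent histones, homologous recombination and Fanconi repair, the replication checkpoint, the RB pathway, p53 targets, interferon-stimulated genes, NF-kB targets, the integrated stress response (ATF4 targets), cholesterol synthesis, the oestrogen response, epithelial and luminal markers, mesenchymal markers, immediate early genes, and mitochondrially encoded genes. Each was tested with camera at a preset correlation of 0.01 between genes, and with an estimated correlation, with adjustment over the 16 lists of a contrast. The lists share members, such as CDKN1A and CCNE1. The estimated-correlation p-values of the paired fit were added after seeing the data.

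Alternatives were DESeq2 1.42.0, relative log expression (RLE) size factors, no low-count filter, leaving out each library, only the groups compared, vehicle libraries of the other month added, and, in the paired fit, each of the first 3 again and leaving out each replicate number. Those made within the paired fit, and a term for COMB beyond the sum of the single agents, were chosen after seeing the data. Both fits were tested on simulated data with 200 changed genes. Genes at 0 counts in a group are given as at least a fold, against a floor of 3 counts over the group. Such floors cover counting error only. No library was left out, and reads were not available.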

Results

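RNA-seq counts were available for 57 libraries in 19 groups of 3, with library totals of 15937770 to 42213423 counts. MB231 (MDA-MB-231) and BT549 (BT-549) are mesenchymal-like breast cancer lines, MCF7 (MCF-7) is a luminal, oestrogen-responsive line, and MCF7PR is labelled as palbociclib-resistant MCF-7. Palbociclib inhibits the kinases CDK4 and CDK6. PKMYT1, the target of MYTi, is a kinase that holds CDK1 inactive before mitosis. ATR, the target of ATRi, is a kinase that signals stalled replication forks. The series concerns Rb1 deficiency and joint inhibition of both kinases, and the labels do not state which lines were taken as deficient. The labels call the replicates biological without saying whether they were separate cultures, so p-values measure only the spread between these libraries.

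RB1, which encodes the retinoblastoma protein (ENSG00000139687.15, GRCh38 chromosome 13, 48303726 to 48599436), was the gene the series is about. Its level in May vehicle libraries was 90.4 ± 5.21 CPM in MB231, 55.4 ± 13.4 in MCF7, 28.8 ± 2.71 in BT549 and 4.73 ± 1.36 in MCF7PR (SD, n = 3 each). Vehicle libraries of other months gave 28.3 ± 6.14 CPM in BT549 (Jan), 51.9 ± 4.79 in MCF7 (Apr) and 29.4 ± 3.10 in MCF7PR (Apr). RB1 was not called in any line for COMB against DMSO, with paired log2 changes of -0.06 in MB231, -0.33 in BT549, 0.08 in MCF7 and 0.35 in MCF7PR. An RNA level does not show whether functional protein is made.

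**Figure D1:**
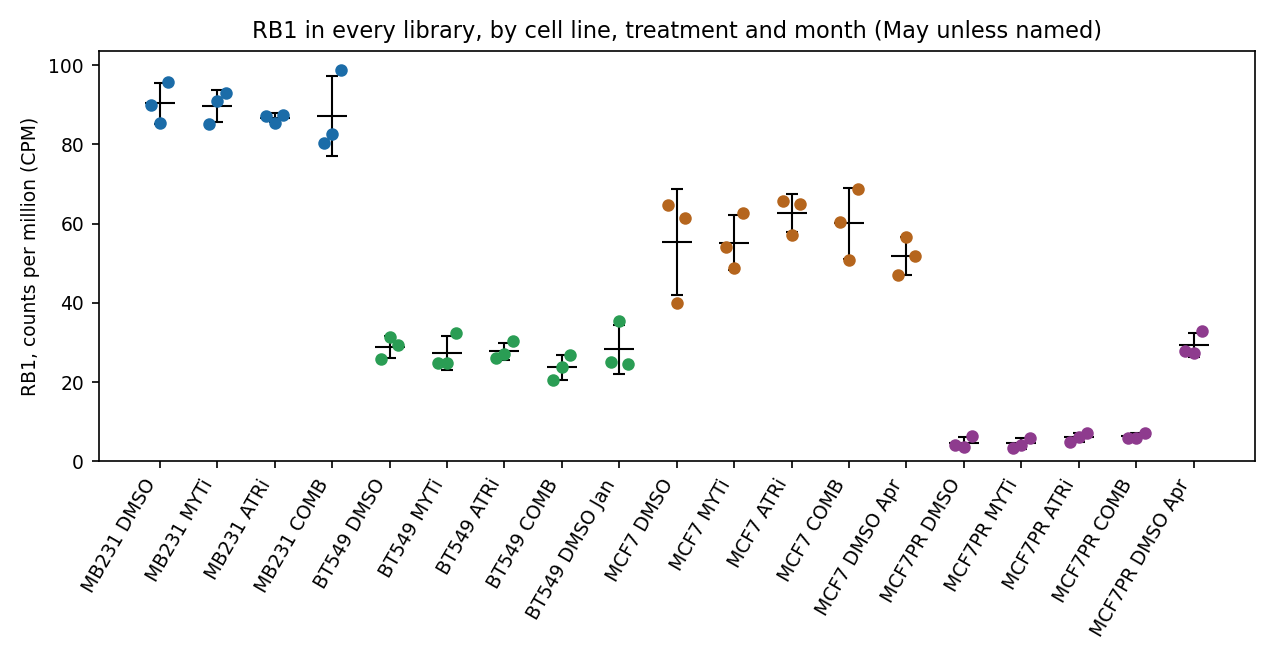
RB1 level (CPM) in each of the 57 libraries, by group, with dots for libraries and bars for mean ± SD. The 3 May vehicle libraries of MCF7PR average 4.73 CPM, against 29.4 in April.

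MB231 had the highest RB1 level, and COMB against DMSO asks what joint inhibition changed there. In the paired fit EGR1, an immediate early transcription factor (ENSG00000120738.7, chromosome 5, 138465490 to 138469315), rose by 1.80 ± 0.18 on the log2 scale (adjusted p = 1.83e-05), from 17.9 ± 5.83 to 61.9 ± 18.1 CPM (SD, n = 3). The dehydrogenase DHRS2 rose by 2.88 ± 0.23 (adjusted p = 1.45e-06) and PTGS2, an inflammatory enzyme, by 1.18 ± 0.22 (adjusted p = 0.00383). HSPA6, a heat shock gene with near-identical paralogs, rose by 4.75 ± 0.42 (adjusted p = 4.45e-06) from 0.31 CPM. Among the largest falls were CDA, a cytidine deaminase (log2 change -1.10 ± 0.19, adjusted p = 0.00207), the surface proteoglycan CSPG4 (-1.05 ± 0.15, adjusted p = 0.00082) and the proton pump subunit ATP6V0A4 (-1.41). Each of these moved the same way in all 3 pairs, which the paired form of the naming rule requires of the largest changes, so it adds no support. CDKN1A, which encodes the CDK inhibitor p21, rose from 44.0 ± 4.35 to 59.3 ± 4.99 CPM (log2 change 0.43 ± 0.07, adjusted p = 0.00109). The mitotic kinase gene CDK1 fell from 216 to 181 CPM (-0.26 ± 0.06, adjusted p = 0.0158), and PKMYT1 fell (-0.36, adjusted p = 0.0348), though 31.6% of its exon length overlaps another gene. ATR, WEE1, CHEK1, CCNE1, E2F1 and MKI67 were not called.

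By list, NF-kB targets had 9 of 20 members higher and 0 lower in MB231 (11 and 0 adjusted over the list alone), among them the chemokine gene CXCL8 (log2 change 0.58 ± 0.10, adjusted p = 0.00189) and BIRC3. The list test gave adjusted p = 0.0803 with an estimated correlation in the paired fit, the lowest of the 16 lists, so none passed in MB231. G2 and mitosis genes had 7 of 30 lower (9 over the list alone), with UBE2C at 205 and 164 CPM, and adjusted p = 0.287 with an estimated correlation. E2F targets had 4 of 36 lower, including CDC25A (113 to 90.1 CPM), and 1 higher (7 and 1 over the list alone). Homologous recombination genes had 4 of 20 lower (6 over the list alone), including FANCD2 and EXO1, and cholesterol synthesis 4 of 20 higher (6 over the list alone). Immediate early genes had 3 of 18 higher and 1 lower (6 and 3 over the list alone). Mitochondrially encoded genes had 4 of 13 lower (9 over the list alone), with MT-CYB at 1748 and 1365 CPM. The mitochondrial share of counts was 3.94, 4.86 and 3.75% in vehicle and 3.30, 4.71 and 3.18% in COMB, lower in each pair. The histone list had 1 of 12 higher, p53 targets 2 of 23 higher and 1 lower, interferon genes 2 of 24 higher, and the oestrogen list 0 of 13.

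The unpaired edgeR fit called 0 genes for COMB in MB231, with 1262 at an unadjusted p under 0.05, and DESeq2 called 38. The paired fit called 916, 444 higher and 472 lower, of which 48 changed at least 2-fold. The paired count rests on single replicate numbers: it was 2459 without replicate 1, 7 without replicate 2 and 382 without replicate 3.

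In BT549, COMB against DMSO raised immediate early genes, NF-kB targets and histone genes in the paired fit, and with an estimated correlation none of these lists passed unpaired. EGR1 rose from 19.9 ± 8.90 to 222 ± 96.4 CPM (SD, n = 3; paired log2 change 3.43 ± 0.33, adjusted p = 0.000443), and its relative EGR2 by 4.94 ± 0.43 (adjusted p = 0.000284, and 0.0320 in the unpaired fit). LIF, a cytokine gene, rose from 9.61 to 73.4 CPM (3.12 ± 0.37, adjusted p = 0.00104). CCL20, a chemokine gene, rose by 4.75 and the activity-regulated gene ARC by 3.79. PCDH18, a protocadherin gene, fell from 23.6 to 5.01 CPM (-2.39, with an unpaired adjusted p = 0.0343), and SAMD9L, an antiviral gene, by 2.49 on the log2 scale. CDK1 (ENSG00000170312.15, chromosome 10, 60778331 to 60794852) fell from 331 ± 38.9 to 220 ± 6.90 CPM (-0.63 ± 0.10, adjusted p = 0.0047). CDKN1A (ENSG00000124762.13, chromosome 6, 36676460 to 36687339) rose from 15.7 ± 7.91 to 45.6 ± 10.8 CPM (1.66 ± 0.32, adjusted p = 0.00855). ATR itself (ENSG00000175054.14, chromosome 3, 142449235 to 142578826) fell (-0.42 ± 0.11, adjusted p = 0.0272). RB1 (adjusted p = 0.0667), WEE1 (0.0516) and MKI67 (0.0611) were not called. With January vehicle libraries added to the unpaired fit, the calls of PCDH18 (adjusted p = 0.078), CDK1 (0.245), BBC3 (0.645), NFKBIA (0.273) and ZFP36 (0.115) were lost.

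Among the lists in BT549, replication-dependent histone genes had 14 of 20 higher and 0 lower (16 over the list alone), with H2BC4 higher by 2.29 ± 0.18 and a list median of 1.35 on the log2 scale. The histone share of counts went from 0.0310, 0.0314 and 0.0294% in vehicle to 0.0640, 0.0848 and 0.0633% in COMB. Immediate early genes had 16 of 19 higher (17 over the list alone), including JUNB and ZFP36, and NF-kB targets 11 of 16 higher (14 over the list alone), including CXCL2 and NFKBIA. These 3 lists each had adjusted p = 0.0287 with an estimated correlation in the paired fit, and 0.104, 0.104 and 0.185 in the unpaired one. Stress response genes had 7 of 20 higher (8 over the list alone), including ATF3 and DDIT3, and p53 targets 6 of 24 higher and 1 lower (8 and 2 over the list alone), including BBC3 and SESN2. Mesenchymal genes had 7 of 18 lower and 2 higher (8 and 2 over the list alone), with COL1A2 at 764 and 354 CPM and CAV1 at 733 and 346. The stress response, p53 and mesenchymal lists had adjusted p = 0.194, 0.118 and 0.191 with an estimated correlation in the paired fit, and none of the remaining lists passed in BT549. G2 and mitosis genes had 4 of 30 lower, among them TOP2A, E2F targets 4 of 36 lower, and homologous recombination genes 3 of 20 lower, among them POLQ (8, 4 and 6 over the list alone). Interferon genes had a list median of -0.99 with 2 of 31 lower, and adjusted p = 0.366 with an estimated correlation. The medians of pairs 1, 2 and 3 were -0.99, -2.48 and -0.07. Neither cholesterol synthesis (0 of 19), the oestrogen list (0 of 11) nor the epithelial list (0 of 5) had a called member in BT549, and mitochondrial genes had 2 of 13 lower (5 over the list alone). The mitochondrial share of counts was 3.63 to 4.30% in vehicle and lower in COMB in each pair.

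The unpaired fit called 220 genes for COMB in BT549, 109 higher and 111 lower, and the paired fit 1681, 821 and 860, of which 439 changed at least 2-fold, and unpaired DESeq2 905. The unpaired count fell to 0 without vehicle replicate 1, 0 without vehicle replicate 2, 6 without vehicle replicate 3, 3 without COMB replicate 1 and 10 without COMB replicate 2. The paired count was 32 without replicate 1 and 416 without replicate 3.

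In MCF7, COMB against DMSO lowered S-phase and mitosis genes. MCM7, a subunit of the replicative helicase, fell from 978 to 705 CPM (paired log2 change -0.52 ± 0.04, and an unpaired adjusted p = 0.0106). CDK1 fell from 152 to 113 CPM (-0.47 ± 0.06, unpaired adjusted p = 0.0103). APOBEC3B, a DNA cytosine deaminase gene, fell from 15.6 ± 1.31 to 8.12 ± 0.768 CPM (SD, n = 3; -0.99 ± 0.12, unpaired adjusted p = 0.00704). CDKN1A rose from 96.5 ± 12.2 to 173 ± 24.7 CPM (0.79 ± 0.07, paired adjusted p = 3e-07, and 0.0351 unpaired). A2M, a protease inhibitor gene, rose by 1.66 ± 0.26 (unpaired adjusted p = 0.0105), and TFF1, an oestrogen target, from 245 to 419 CPM (0.73 ± 0.06). E2F1 (-0.42, adjusted p = 0.000175), PKMYT1 (-0.48), CHEK1 (-0.28, adjusted p = 0.00435) and WEE1 (-0.23, adjusted p = 0.0185) fell, while ATR, CCNE1 and MKI67 were not called. With April vehicle libraries added to the unpaired fit, the calls of CDK1 (adjusted p = 0.172) and PKMYT1 (0.0549) were lost, as was that of EGR1 (0.388).

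Of the E2F targets 30 of 36 fell in MCF7 and 0 rose (31 over the list alone), and 17 fell in the unpaired fit (29 over the list alone). Of G2 and mitosis genes 23 of 30 fell (26 over the list alone), including PLK1 and UBE2C, and 14 fell in the unpaired fit (22 over the list alone). Of p53 targets 14 of 25 rose and 0 fell (19 over the list alone), including GDF15 and TP53INP1, and 9 rose in the unpaired fit (15 over the list alone). These 3 lists had adjusted p = 0.00558, 0.0150 and 0.0208 with an estimated correlation unpaired, and 0.0156 each when paired. Replication checkpoint genes had 9 of 20 lower (10 over the list alone), including CDC25B, and homologous recombination genes 9 of 20 lower (13 over the list alone), including FANCG. Cholesterol synthesis had 15 of 19 lower (15 over the list alone), including EBP and DHCR7, and histones 8 of 20 higher (9 over the list alone), including H3C10. Stress response genes had 9 of 19 lower and 3 higher (10 and 4 over the list alone), including the serine synthesis gene PHGDH (-0.71). The oestrogen list had 7 of 18 higher (8 over the list alone), RB pathway genes 4 of 18 higher and 5 lower, with CDK6 higher, and epithelial genes 1 of 17 higher and 4 lower, with KRT8 lower. NF-kB targets had 5 of 13 higher and 1 lower, interferon genes 3 of 29 higher, immediate early genes 4 of 18 higher and mesenchymal genes 1 of 12 higher. In the paired fit the histone list had adjusted p = 0.0169 with an estimated correlation, checkpoint and NF-kB 0.0291 each and cholesterol and oestrogen 0.0363 each, and none of these 5 passed unpaired. The remaining lists passed in neither fit, including homologous recombination (0.128) and stress response (0.06). Mitochondrial genes had 5 of 13 higher (8 over the list alone), and the mitochondrial share of counts was 5.45, 5.98 and 4.86% in vehicle and 6.87, 6.92 and 5.61% in COMB. The unpaired fit called 252 genes, 77 higher and 175 lower, but 11 with only the 2 groups compared and 623 with DESeq2, and the paired fit 3012, 1344 and 1668. The unpaired count was 76, 122 and 136 without vehicle replicates 1, 2 and 3, and 2, 137 and 81 without COMB replicates 1, 2 and 3. The paired count was 1313 without replicate 1 and 1950 without replicate 2.

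In MCF7PR, which had the lowest RB1 level among May vehicle libraries, COMB against DMSO raised immediate early genes, NF-kB targets and histone genes in the paired fit. Of these lists only the immediate early one also passed in the unpaired fit (adjusted p = 0.00162 with an estimated correlation). IFIT1, an antiviral effector gene (ENSG00000185745.9, chromosome 10, 89392546 to 89406486), rose from 7.08 ± 5.94 to 41.9 ± 9.84 CPM (SD, n = 3; paired adjusted p = 5.33e-06). CXCL8 rose from 6.84 to 46.0 CPM (2.68 ± 0.14, adjusted p = 8.25e-10) and the stress regulator ATF3 from 12.8 to 91.3 CPM (2.86 ± 0.26). MMP3, a matrix protease gene, rose by 3.57 ± 0.39 (adjusted p = 4.13e-06) and the chemokine gene CCL5 by 2.85. STAC2 fell from 40.2 to 7.21 CPM (-2.53), the basal keratin genes KRT5 and KRT6A by 1.74 and 1.70 on the log2 scale, and IGFBP5, a growth factor binding gene, by 1.72. CCNE1 rose (0.45 ± 0.10, adjusted p = 0.00291), as did CDKN1A, from 430 ± 274 to 747 ± 145 CPM (0.89 ± 0.17, adjusted p = 0.000612). CDK1 (-0.38, adjusted p = 0.0111) and PKMYT1 (-0.58, adjusted p = 0.000128) fell. E2F1 (adjusted p = 0.0542), ATR, WEE1, CHEK1 and MKI67 were not called.

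Interferon genes had 24 of 31 higher and 0 lower in MCF7PR (25 over the list alone), among them ISG20, from 8.63 to 27.8 CPM (log2 change 1.64 ± 0.12, adjusted p = 1.32e-07), IFIH1 and IFIT2. The list test gave adjusted p = 0.0915 with an estimated correlation unpaired and 0.0511 paired. NF-kB targets had 18 of 20 higher (18 over the list alone), including TNFAIP3, histones 12 of 18 higher (15 over the list alone), including H2BC12 at 17.5 and 37.7 CPM, and immediate early genes 16 of 19 higher and 1 lower (17 and 1 over the list alone), including NR4A1. These 3 lists had adjusted p = 0.0293, 0.0411 and 0.0293 with an estimated correlation in the paired fit, and of them the immediate early list also in the unpaired one (0.00162). Of p53 targets 16 of 25 rose and 1 fell (20 and 1 over the list alone), including BTG2 and PPM1D, and of stress response genes 11 of 20 rose and 1 fell (12 and 2), including PPP1R15A, but these lists had adjusted p = 0.226 and 0.194 with an estimated correlation in the paired fit. E2F targets split, with 7 of 36 higher, among them CCNE2 and E2F7, and 7 lower (7 and 8 over the list alone). G2 and mitosis genes had 10 of 30 lower and 1 higher, including TOP2A, and homologous recombination genes 8 of 20 lower (9 over the list alone), including BRCA1. These lists had adjusted p = 0.674 and 0.451 with an estimated correlation, and the medians of pairs 1, 2 and 3 were -0.47, -0.09 and 0.21 for the first and -0.46, -0.29 and 0.09 for the second. Mesenchymal genes had 10 of 15 lower, including COL1A1, cholesterol synthesis 8 of 19 higher and 1 lower, including LDLR, and the oestrogen list 4 of 17 higher and 5 lower. Their adjusted p was 0.0542, 0.281 and 0.337 with an estimated correlation. Epithelial genes had 1 of 14 higher and 3 lower, RB pathway genes 5 of 21 higher and 3 lower, and replication checkpoint genes 3 of 20 higher and 5 lower. All 13 mitochondrial genes fell, with a list median of -0.51, and the list had adjusted p = 0.194 with an estimated correlation paired and 0.443 unpaired. The mitochondrial share of counts went from 6.19, 4.06 and 6.17% in vehicle to 4.98, 3.04 and 5.94% in COMB. The unpaired edgeR fit called 0 genes, with 1623 at an unadjusted p under 0.05, and DESeq2 227. The paired fit called 4523, 2008 higher and 2515 lower, of which 552 changed at least 2-fold. It called 2724 without replicate 1 and 2192 without replicate 2, and the unpaired fit 1 without vehicle replicate 3.

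**Figure D2:**
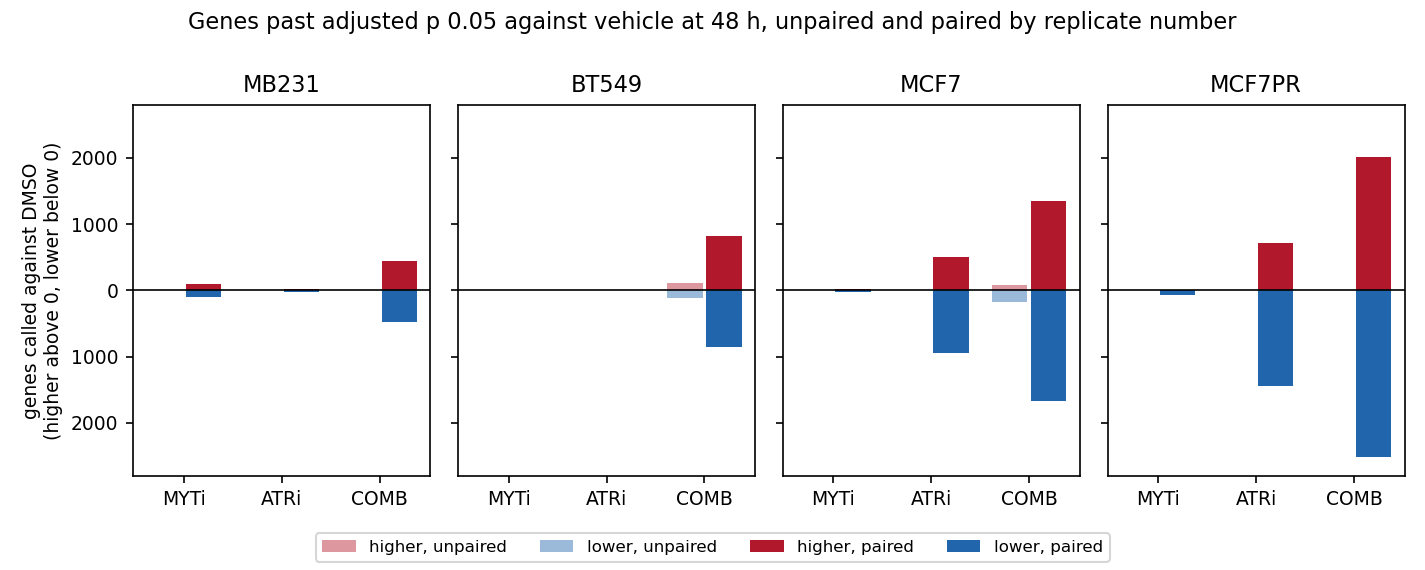
Genes higher and lower than DMSO per line (bars, number of genes) for MYTi, ATRi and COMB, with the unpaired fit in pale and the paired fit in solid colour. COMB called 4523 genes in MCF7PR, 3012 in MCF7, 1681 in BT549 and 916 in MB231 in the paired fit.

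**Figure D3:**
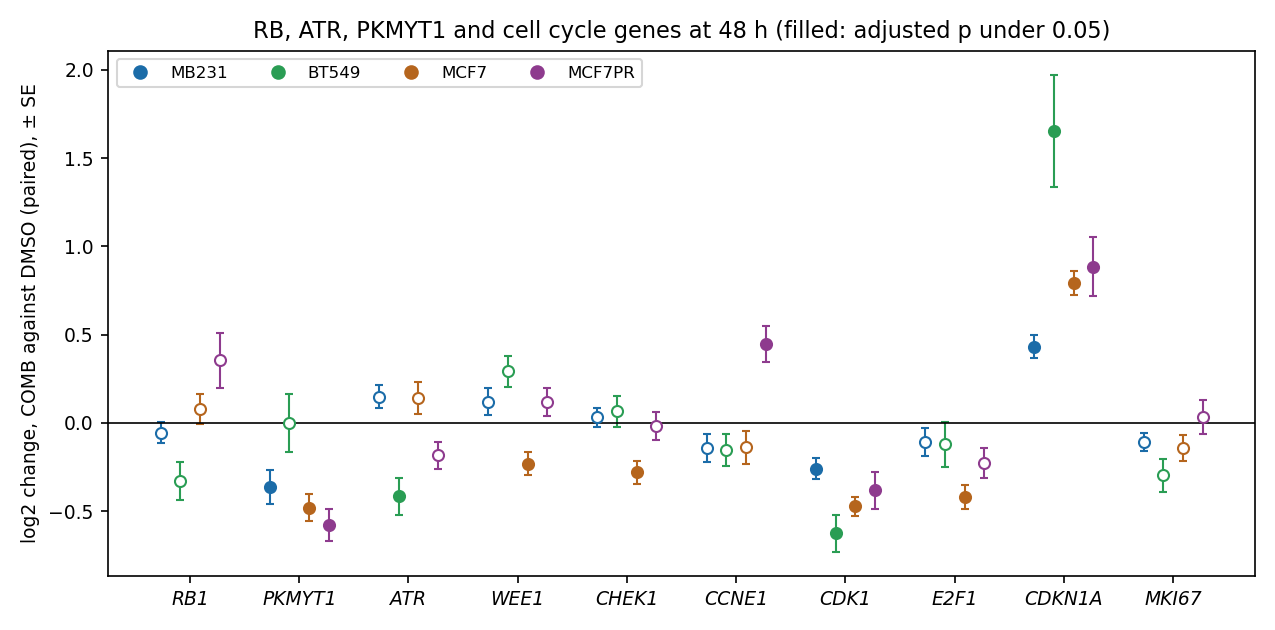
Paired log2 change (COMB against DMSO) ± SE for the 10 genes named in every comparison, in 4 lines, filled where the adjusted p was under 0.05. CDKN1A is higher and CDK1 lower in each line.

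Across lines, 19 genes rose with COMB in all 4, against 0.25 expected by chance among the 12522 genes tested in each. They include the CDK inhibitor gene CDKN1A, the immediate early genes EGR1 and JUNB, the survival gene MCL1, BIRC3, the autophagy receptor gene SQSTM1 and the histone gene H4C8. The 7 genes that fell in all 4, against 0.407 expected, were CDK1, its activating phosphatase gene CDC25B (ENSG00000101224.17, chromosome 20, 3786772 to 3806121), CIT, NEURL1B, QPCTL, RBBP4 and TRIP13. BT549 and MCF7PR shared 334 higher genes against 92.2 expected, and MCF7 and MCF7PR 477 lower genes against 263.5 expected. MB231 and BT549 shared 68 higher genes against 22.7 expected. MB231 and MCF7PR shared 155 higher genes against 54.4 expected and 162 lower genes against 69.6. MB231 and MCF7 shared 87 higher genes against 38.1 and 97 lower against 46, and MB231 and BT549 63 lower against 23.7. BT549 and MCF7PR shared 252 lower genes against 122.5, and BT549 and MCF7 123 higher against 62.9. Closest to the expected number were 115 lower genes in BT549 and MCF7 against 81 expected, and 220 higher genes in MCF7 and MCF7PR against 154.7. Genes called in opposite directions were fewer than expected in each pair of lines, but near it in BT549 and MCF7 (138 against 144.1). All these overlaps rest on the paired fits. The sets shared by all 4 lines need calls in MB231, where the paired count for COMB was 7 without replicate 2 and another arrangement within pairs called 422 genes. These counts of genes called in 1 line and not another are not tests of a difference.

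**Figure D4:**
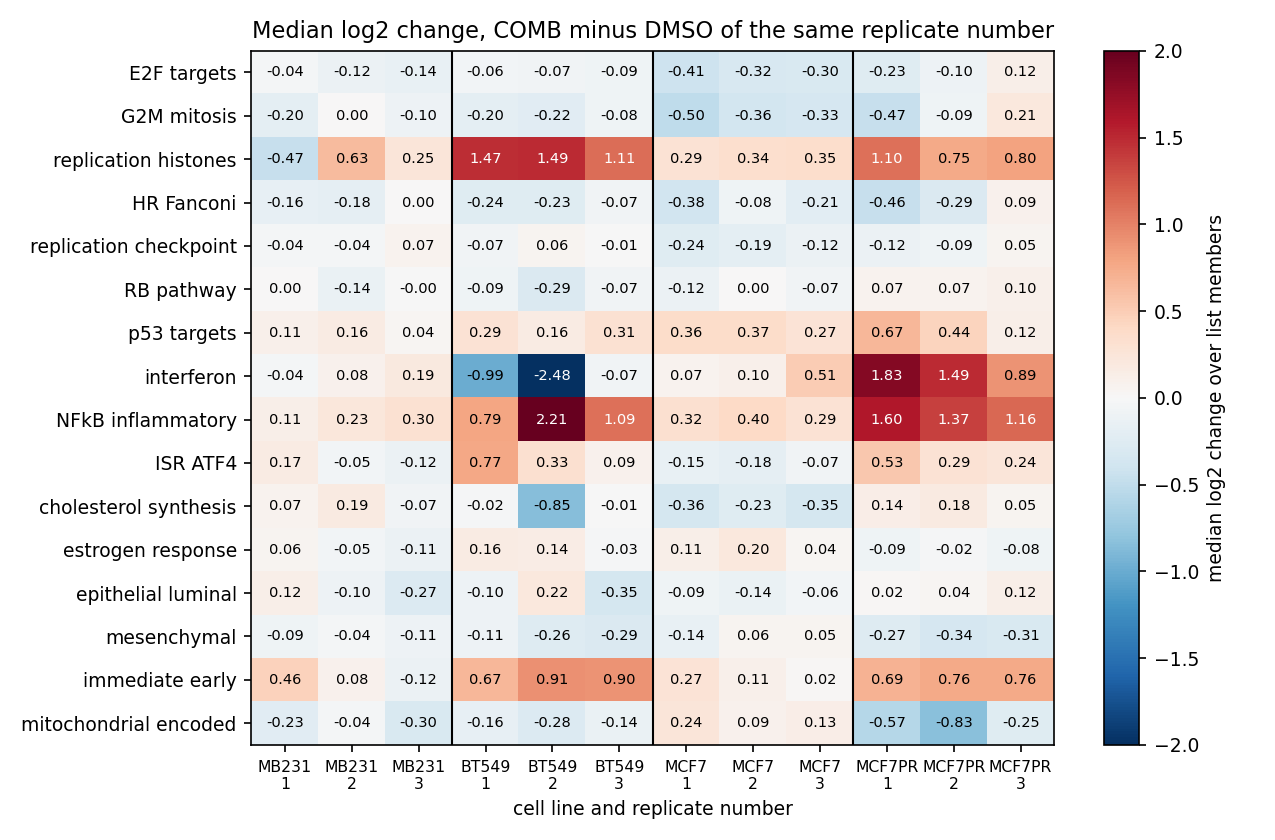
Median log2 change (COMB minus DMSO) of each of the 16 gene lists in each of the 12 pairs of libraries, as a colour scale. The interferon list lies at 0.89 to 1.83 in the MCF7PR pairs and at 0.07 to 0.51 in the MCF7 pairs.

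Whether MCF7PR and MCF7 responded differently to COMB was tested directly. The unpaired fit called 16 genes, but 0 with only the 4 groups of the contrast, 10 with RLE factors and 119 with DESeq2. The cytosine deaminase gene APOBEC3B had a difference of 2.08 on the log2 scale (adjusted p = 0.0222) and the GTPase gene RND1 of 2.18 (adjusted p = 0.0418). The cadherin gene CELSR2 had -1.09 (adjusted p = 0.0145), and EPHB3, an ephrin receptor gene, 1.00 (adjusted p = 0.0185). In the paired fit the viral RNA sensor gene IFIH1 differed by 1.46 (adjusted p = 3.57e-06), ISG20 by 1.58 (adjusted p = 6.62e-06) and the LDL receptor gene LDLR by 0.99 (adjusted p = 7.57e-07). RRM2, which supplies deoxynucleotides, differed by 0.92 (adjusted p = 2.25e-05), CCNE1 by 0.60 (adjusted p = 0.0051) and WEE1 by 0.37 (adjusted p = 0.0141), all higher in MCF7PR relative to MCF7. The difference for CDK1 (0.10) and CDKN1A (0.11) was not called.

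By list, the paired difference was positive for 22 of 36 E2F targets (23 over the list alone), 17 of 19 cholesterol genes (17), 15 of 31 interferon genes (16), 12 of 20 stress response genes (13), 11 of 19 immediate early genes (13) and 6 of 21 histones (7). It was negative for all 13 mitochondrial genes and for 7 of 19 oestrogen genes (8 over the list alone). With an estimated correlation in the paired fit, the cholesterol and histone lists had adjusted p = 0.0208, immediate early 0.0329 and stress response 0.0453, and interferon, E2F targets and mitochondrial genes had adjusted p = 0.0541 and oestrogen genes adjusted p = 0.0515 with an estimated correlation. None passed unpaired. The paired fit called 3077 genes, 1539 positive and 1538 negative, with 2046 without MCF7PR replicate 2 and 1836 without MCF7 replicate 1. The unpaired 16 became 8, 0 and 3 without MCF7 vehicle replicates 1, 2 and 3, and 0, 3 and 0 without MCF7 COMB replicates 1, 2 and 3. It became 4, 5 and 4 without MCF7PR vehicle replicates 1, 2 and 3, and 7 and 6 without MCF7PR COMB replicates 1 and 2.

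The same test for BT549 against MB231 gave larger responses of inflammatory genes in BT549 in the paired fit. In the paired fit LIF differed by 3.08 (adjusted p = 0.000479) and TNFAIP3, an NF-kB feedback gene, by 2.46 (adjusted p = 0.000479). CDKN1A differed by 1.20 (adjusted p = 0.0399). CAV1, a membrane coat gene, differed by -1.11 (adjusted p = 0.000479), ATR by -0.58 (adjusted p = 0.0102) and IFIT1 by -2.47 (adjusted p = 0.0463). NF-kB targets had 9 of 20 with a positive difference (14 over the list alone), immediate early genes 11 of 19 (15) and histones 8 of 20 (8). The first 2 had adjusted p = 0.0412 with an estimated correlation in the paired fit, and histones had adjusted p = 0.259 with an estimated correlation. None of the 3 passed unpaired. The unpaired edgeR fit called 0 genes, with 2008 at an unadjusted p under 0.05, and DESeq2 193. The unpaired count was 87 without BT549 COMB replicate 3 and 3 without MB231 COMB replicate 1. The paired fit called 1028, 452 positive and 576 negative, with 655 without BT549 replicate 1 and 625, 134 and 78 without MB231 replicates 1, 2 and 3.

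PKMYT1 inhibition alone (MYTi against DMSO) changed few genes. In MB231 the secreted mucin gene MUC5AC rose by 1.78 and DHRS2 by 1.34 in the paired fit, while the signalling regulator RGS4 fell by 1.11 on the log2 scale. In BT549 EGR2 alone was called (4.26 ± 0.44, adjusted p = 0.0063). In MCF7 EGR1 rose by 0.78 (adjusted p = 1.14e-05) and A2M by 1.47, and APOBEC3B fell (-0.64). In MCF7PR CXCL8 rose by 0.86, and KRT6A and KRT5 fell (-1.35 and -1.16). Mitochondrial genes had 9 of 13 lower in MB231 (12 over the list alone), with adjusted p = 0.0946 with an estimated correlation paired and 0.281 unpaired. Histones in BT549 had 0 of 20 called (13 higher over the list alone), with adjusted p = 0.0465 with an estimated correlation paired and 0.0739 unpaired. Paired counts were 196 in MB231, 1 in BT549, 41 in MCF7 and 81 in MCF7PR. Unpaired edgeR called 0 in each, with 464, 283, 495 and 163 at an unadjusted p under 0.05, and DESeq2 2, 3, 8 and 0. The paired count in MB231 was 2 without replicate 2 and 64 without replicate 3, and in BT549 0, 7 and 0 without replicates 1, 2 and 3. It was 5 and 17 in MCF7 without replicates 1 and 3, and 25, 8 and 173 in MCF7PR without replicates 1, 2 and 3.

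ATR inhibition alone changed more genes in MCF7 and MCF7PR. In MCF7PR the antiviral genes IFIT1 and IFIT2 rose by 1.90 (adjusted p = 0.000858) and 1.82, MMP3 rose by 2.12, and STAC2 fell (-1.34). In MCF7 the histone gene H4C16 rose by 0.93, and the transcription factor gene FOXD1 fell (-0.87, adjusted p = 0.000208). In MB231 HSPA6 rose by 4.56, DHRS2 by 2.14 and EGR1 by 1.03, and CDA fell (-0.89). Interferon genes had 18 of 31 higher in MCF7PR (20 over the list alone), and NF-kB targets 10 of 20 (13 over the list alone), with adjusted p = 0.126 and 0.121 with an estimated correlation. Immediate early genes had 6 of 19 higher in MCF7PR (11 over the list alone), with adjusted p = 0.0369 with an estimated correlation unpaired but 0.126 paired. Histones had 8 of 20 higher in MCF7 (9 over the list alone), and E2F targets 9 of 36 lower (14 over the list alone), with adjusted p = 0.0414 and 0.149 with an estimated correlation paired and 0.193 each unpaired. Mitochondrial genes had 9 of 13 lower in MB231 (12 over the list alone), with adjusted p = 0.0425 with an estimated correlation paired and 0.221 unpaired. NF-kB targets there had 0 of 20 called (10 higher over the list alone), with adjusted p = 0.0425 with an estimated correlation paired and 0.438 unpaired. Paired counts were 40 in MB231, 0 in BT549, 1451 in MCF7 and 2157 in MCF7PR, with 1449 genes at an unadjusted p under 0.05 in BT549. Unpaired edgeR called 0 in each, with 381, 704, 1563 and 746 at an unadjusted p under 0.05, and DESeq2 1, 1, 43 and 3. In paired BT549, DESeq2 called 62. The paired count in MB231 was 2 and 75 without replicates 2 and 3, in BT549 1 without replicate 2, in MCF7 260 and 275 without replicates 1 and 2, and in MCF7PR 825 and 563 without replicates 1 and 2.

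COMB was compared with each single agent to ask what the added drug changed. Over MYTi, ATF3 rose by 2.28 and IFIT2 by 2.36 in MCF7PR, TRAF1, an NF-kB pathway gene, by 2.38 in BT549, and HSPA6 by 4.61 in MB231. The microtubule gene MAP2 fell in BT549 (-1.38), STAC2 in MCF7PR (-1.43), the Rho effector gene CDC42EP5 in MCF7 (-1.32) and the laminin gene LAMA5 in MB231 (-0.74). In MCF7 25 of 36 E2F targets fell relative to MYTi (29 over the list alone), and in MCF7PR 25 of 31 interferon genes rose (25 over the list alone). These lists had adjusted p = 0.00974 and 0.0405 with an estimated correlation unpaired, and 0.0197 and 0.0226 paired. Immediate early genes in MCF7PR had 14 of 19 higher (17 over the list alone), with adjusted p = 0.00222 with an estimated correlation unpaired and 0.0209 paired. Paired counts over MYTi were 70 in MB231, 89 in BT549, 1348 in MCF7 and 2531 in MCF7PR. Unpaired edgeR called 0 in each, with 644, 1575, 1413 and 841 at an unadjusted p under 0.05, and DESeq2 1, 101, 102 and 17. Without replicates 1, 2 and 3 the paired count was 1746, 0 and 8 in MB231 and 0, 649 and 0 in BT549. It was 40 in MCF7 without replicate 1, and 364 and 670 in MCF7PR without replicates 1 and 2. The unpaired count in MCF7 was 1 without COMB replicate 2.

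Over ATRi, CXCL8 rose by 0.99 (adjusted p = 0.00166), ATF3 by 1.09 and MMP3 by 1.46 in MCF7PR, A2M by 1.31 in MCF7 and EGR1 by 0.77 in MB231. The cell adhesion gene NCAM1 fell in MCF7 (-1.02), KISS1 in MB231 (-0.68) and the focal adhesion gene TNS3 in MCF7PR (-0.58). In MCF7 20 of 30 G2 and mitosis genes fell (29 over the list alone) and 13 of 36 E2F targets (30 over the list alone), each with adjusted p = 0.0147 with an estimated correlation unpaired, and 0.0241 and 0.0291 paired. Immediate early genes in MCF7PR had 4 of 19 higher (12 over the list alone), with adjusted p = 0.00535 with an estimated correlation unpaired but 0.0759 paired. Interferon genes in BT549 had 0 of 31 called and 27 lower over the list alone, with adjusted p = 0.167 with an estimated correlation. Paired counts over ATRi were 120 in MB231, 0 in BT549 (2157 at an unadjusted p under 0.05, and 318 by paired DESeq2), 473 in MCF7 and 99 in MCF7PR. Unpaired edgeR called 0 in each, with 918, 1152, 1091 and 190 at an unadjusted p under 0.05, and DESeq2 1, 13, 49 and 1. The paired count was 2044, 0 and 1 in MB231 without replicates 1, 2 and 3, 654 in BT549 without replicate 2, 22 in MCF7 without replicate 1, and 53 and 2 in MCF7PR without replicates 1 and 2. The unpaired count in MB231 was 47 without COMB replicate 1. Changes beyond the sum of both single agents were called at 44 genes in MB231 (14 higher, 30 lower) and 0 in BT549, MCF7 and MCF7PR in the paired edgeR fit, where 612, 1129 and 1184 genes had an unadjusted p under 0.05. The unpaired fit called 0 in each, with 566, 228, 289 and 87. DESeq2 was not run for this term.

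MCF7PR and MCF7 were compared in vehicle over 12 libraries of both months, to ask how the resistant line differs without drug. The membrane protein gene EMC10 (ENSG00000161671.16) and the cytokine receptor gene IL7R had 0 counts in MCF7 and were at least 4570-fold and 3430-fold higher in MCF7PR. The oestrogen target TFF1 (ENSG00000160182.2) and the luminal factor gene ELF5 had 0 counts in MCF7PR and were at least 7690-fold and 2290-fold lower. The luminal regulators GATA3 (68.7 and 1384 CPM in May; log2 difference -4.03 ± 0.22) and FOXA1 (-6.97 ± 0.40) were lower, as was the sterol synthesis gene HMGCS1 (22.9 and 688 CPM). FOSL1, an AP-1 subunit gene, was higher (7.59 ± 0.42), as was LIF (5.82 ± 0.47). RB1 was lower (-2.04 ± 0.43, adjusted p = 0.000789), at 8.54% of the MCF7 level in May and 56.6% in April. Also lower were CDK1 (-1.12, adjusted p = 0.0007), CHEK1 (-0.92), WEE1 (-0.59, adjusted p = 0.000452) and E2F1 (-0.55, adjusted p = 0.00397). CCNE1 was higher (1.82 ± 0.18, adjusted p = 5.44e-07), as was CDKN1A (1.70 ± 0.25, adjusted p = 2.93e-05). PKMYT1 (ENSG00000127564.16, chromosome 16, 2968024 to 2980539; adjusted p = 0.0555), ATR and MKI67 were not called.

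In that comparison all 17 epithelial genes were lower (17 over the list alone) and 14 of 16 mesenchymal genes higher and 1 lower (14 and 1 over the list alone), among them the cadherin gene CDH2 at 97.4 and 0.0754 CPM in May. The oestrogen list had 12 of 19 lower and 2 higher (12 and 2 over the list alone). These 3 lists had adjusted p = 0.0166 with an estimated correlation unpaired, and 0.0659 with the replicate number as a block. Cholesterol synthesis had 18 of 19 lower, histones 17 of 20 lower and E2F targets 18 of 36 lower and 4 higher. The histone share of counts was 0.0627% in MCF7PR April replicate 4 and 0.0134 to 0.0263% in the other 5 MCF7PR libraries, against 0.0463 to 0.0621% in MCF7. The p53 list had 20 of 25 higher, including FAS, the interferon list 17 of 30 higher and 4 lower, including ISG15, and NF-kB targets 11 of 15 higher and 1 lower. Over the list alone the counts of these 6 lists were the same but for 21 p53 targets. None of the 6 passed with an estimated correlation, at adjusted p = 0.11, 0.875, 0.875, 0.287, 0.875 and 0.426 with an estimated correlation. RB pathway genes had 6 of 21 higher and 10 lower. Of the 16957 genes tested 10448 were called, 5165 higher and 5283 lower, and 9338 with May libraries only and 7597 with April libraries only.

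BT549 was compared with MB231 in vehicle, to ask how these lines differ without drug. The collagen gene COL1A2 had 0 counts in MB231 and was at least 14700-fold higher in BT549, and CDKN2A, which encodes the CDK inhibitor p16 (ENSG00000147889.17), at least 3830-fold higher, at 200 ± 29.3 CPM (SD, n = 3). BEX3 had 0 counts in BT549 and was at least 2430-fold lower. RB1 was lower (log2 difference -1.67 ± 0.11, adjusted p = 3.34e-07), as were the keratin gene KRT18 (-7.78), the protease inhibitor gene SERPINE1 (-9.98) and CDKN1A (-1.50 ± 0.28, adjusted p = 0.000717). CCNE1 (1.02, adjusted p = 9.28e-06), CDK1 (0.60), E2F1 (0.40) and WEE1 (0.28, adjusted p = 0.0355) were higher, and ATR (-0.32, adjusted p = 0.0230) and CHEK1 (-0.30) lower. PKMYT1 and MKI67 were not called. Histones had 9 of 14 higher and 1 lower (10 and 1 over the list alone), interferon genes 17 of 29 higher and 3 lower, including IFI6, and stress response genes 12 of 20 higher and 3 lower. NF-kB targets had 13 of 20 lower and 2 higher, and epithelial genes 6 of 8 lower, with a median of -6.19, or -5.36 with the 2 members at 0 counts set to their bound. RB pathway genes had 10 of 21 higher and 8 lower. None of these lists passed with an estimated correlation, where the lowest was adjusted p = 0.334 with an estimated correlation for the epithelial list. Of 15457 genes 10238 were called, 5173 higher and 5065 lower.

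Vehicle libraries of the same line differed between months, which shows how far cultures or library batches moved without drug. In BT549 the matrix protein gene SMOC1 was at 0.238 CPM in May and 34.8 ± 18.5 in January (SD, n = 3; log2 difference 7.22 ± 0.62, adjusted p = 0.00155), and the homeobox gene DRGX was lower in January (-5.60 ± 0.60, adjusted p = 0.00347). In MCF7 the transcription factor gene ZBTB16 was higher in April (4.67 ± 0.35, adjusted p = 2.22e-06) and the transporter gene SLC6A14 lower (-4.79 ± 0.31, adjusted p = 4.3e-07). In MCF7PR the glutathione transferase gene MGST1 was higher in April (6.89 ± 0.42, adjusted p = 0.000141) and PEG10, an imprinted gene, lower (-4.83 ± 0.86, adjusted p = 0.0190). RB1 was higher in April in MCF7PR (2.74 ± 0.25, adjusted p = 0.00137), and was not called in MCF7 (-0.10 ± 0.16, adjusted p = 0.755) or between January and May in BT549 (0.04). The counts were 1929 genes in BT549 (1253 higher in January), 1669 in MCF7 (916 higher in April) and 643 in MCF7PR (326 higher in April). The BT549 count was 276, 79 and 363 without May replicates 1, 2 and 3, and 3361 without January replicate 6. The MCF7 count was 785 without May replicate 1 and 1066 without April replicate 4. The MCF7PR count was 145, 134 and 106 without May replicates 1, 2 and 3, and 246 and 350 without April replicates 5 and 6. Each month of a line is 1 set of libraries, so these counts do not separate a culture change from a library batch.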

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

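The comparison of single pairs below was chosen only after the result was seen, as were the exchanges within pairs.

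The results here differed between 2 lines in the test of the difference itself. MCF7PR and MCF7 differed in their response to COMB at 16 genes unpaired and at 3077 with the replicate block (2046 without MCF7PR replicate 2, 1836 without MCF7 replicate 1). Of the 40 splits of the libraries tested for this difference, the real one gave the most genes, with 16 against 8 for the highest other. These splits exchanged vehicle and COMB labels within each line, which also breaks the response shared by both lines. They therefore cannot exclude chance for a difference between the lines. With only the 4 groups of the contrast this count was 0, and 10 with RLE factors. The splits ignored the replicate numbers, and none were run for the paired 3077. In MCF7PR relative to MCF7, the differences on the log2 scale were 2.184 for RND1, 2.079 for APOBEC3B, 1.706 for LRATD1, 1.367 for PCDH1, 1.049 for NOCT and 0.995 for EPHB3. They were -1.303 for RAPGEFL1, -1.175 for NEBL, -1.092 for CELSR2, -0.995 for NCKAP5L and -0.888 for ZNF512B. The unpaired 16 became 0 without MCF7 vehicle replicate 2, MCF7 COMB replicate 1 or MCF7 COMB replicate 3, 8 and 3 without MCF7 vehicle replicates 1 and 3, and 3 without MCF7 COMB replicate 2. It became 4, 5 and 4 without MCF7PR vehicle replicates 1, 2 and 3, and 7 and 6 without MCF7PR COMB replicates 1 and 2.

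By list, the unpaired median difference between MCF7PR and MCF7 was 1.095 for interferon genes, 0.589 for histones, 0.569 for immediate early genes, 0.500 for cholesterol synthesis, 0.444 for the integrated stress response, 0.413 for NF-kB targets and 0.315 for E2F targets. It was -0.284 for the oestrogen list and -0.647 for mitochondrially encoded genes. These lists passed with the preset correlation and none with an estimated one unpaired. The mitochondrial share of counts, a sum over the same genes, fell in the MCF7PR pairs and rose in the MCF7 pairs, and whether RNA quality or the cells differed was not tested.

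The interferon difference was weighed as a pattern: in MCF7PR 24 of 31 members rose with COMB in the paired fit, and the paired median difference was 1.159 with 15 members called, though the list did not pass with an estimated correlation (adjusted p = 0.0541 paired and 0.14 unpaired). If 1 set of cultures decided it, the other MCF7PR pairs would lie within the range of MCF7, but the lowest MCF7PR pair had a median of 0.891 and the highest MCF7 pair 0.514. For unequal depth, each library was thinned to 16650210 counts, which left a median difference of 1.213 with 15 members called among 2893 genes. Thinning lowers all genes of a library alike, so the median was bound to change little and cannot decide on depth. It shows only that as many members were called at equal totals. Over the 23 members at 1 CPM or more in MCF7 vehicle the difference was 1.079 with 13 called, so genes too low to show a rise in MCF7 do not account for it. A response particular to MCF7PR may explain these values, as a hypothesis, and whether the lower RB1, the palbociclib resistance or another difference of that line underlies it was not tested.

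BT549 and MB231 differed in their response to COMB at 1028 genes with the replicate block and at 0 unpaired. In BT549 relative to MB231 the unpaired median differences were 1.459 for NF-kB targets, 1.175 for histones, 0.802 for immediate early genes, 0.342 for the integrated stress response, -0.298 for cholesterol synthesis and -1.202 for interferon genes. With an estimated correlation none of these lists passed unpaired, and NF-kB and immediate early genes passed in the paired fit (adjusted p = 0.0412 with an estimated correlation each). All 40 splits tested gave at least the real unpaired count of 0, and the highest other split called 45, so chance was not excluded for the unpaired result. Any split reaches 0, and the 45 point to a structure of the libraries whose cause was not tested. The paired count was 655 without BT549 replicate 1 and 625, 134 and 78 without MB231 replicates 1, 2 and 3, and the unpaired count 87 without BT549 COMB replicate 3 and 3 without MB231 COMB replicate 1. In the interferon list the medians of the BT549 pairs ran from -2.479 to -0.071.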

How the results depend on the processing

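The paired settings other than the plain replicate block, and the term beyond the sum, were chosen only after the results were seen. No list test or named gene called in the unpaired fit reversed direction under another setting. Results not called in the unpaired fit, and the counts of genes, were not checked for a reversal. Counts are of genes called, and for counts that changed by more than 1.5 times the cause was not tested, except where fewer libraries or genes were used.

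With DESeq2, MB231 gave 2 genes for MYTi, 1 for ATRi, 38 for COMB, 1 for COMB against MYTi and 1 for COMB against ATRi. In the same order BT549 gave 3, 1, 905, 101 and 13, and MCF7 8, 43, 623, 102 and 49. MCF7PR gave 3 for ATRi, 227 for COMB, 17 against MYTi and 1 against ATRi. The difference between MCF7PR and MCF7 gave 119, that between BT549 and MB231 193, BT549 January against May 3052 and MCF7PR April against May 1662. The other 4 counts were within 1.5 times.

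With no low-count filter, MB231 gave 50, 19, 117, 16 and 9 in that order, BT549 67, 170, 1473, 638 and 526, MCF7 19, 96, 780, 179 and 57, and MCF7PR 40 for COMB. The differences gave 169 for MCF7PR and MCF7 and 539 for BT549 and MB231, BT549 by month 3545 and MCF7PR by month 1787. These fits test more genes, most with few counts.

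With the replicate block, MB231 gave 196, 40, 916, 70 and 120, and 44 beyond the sum of single agents. BT549 gave 1 for MYTi, 1681 for COMB and 89 against MYTi. MCF7 gave 41, 1451, 3012, 1348 and 473, MCF7PR 81, 2157, 4523, 2531 and 99, and the differences 3077 and 1028. The block removes the spread between replicate numbers, which correlated at medians of 0.30 to 0.66 within lines.

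In the paired fit with no low-count filter, MB231 gave 401 for MYTi, 182 for ATRi, 521 against MYTi and 779 against ATRi, and BT549 137, 315, 1183 and 922. MCF7 gave 178 for MYTi and 845 against ATRi, and MCF7PR 322 and 461. In the paired fit with DESeq2, MB231 gave 73 for ATRi, 194 against MYTi and 439 against ATRi, and BT549 33 for MYTi, 62 for ATRi, 576 against MYTi and 318 against ATRi. MCF7 gave 76 for MYTi, and MCF7PR 155 for MYTi and 253 against ATRi. The paired COMB counts kept within 1.5 times with DESeq2 (954 in MB231, 1970 in BT549, 2704 in MCF7, 4343 in MCF7PR).

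Adding vehicle libraries of the other month gave 2 genes for MCF7 ATRi and 8 for MCF7PR COMB. With only the compared groups, MCF7 COMB gave 11 genes, the difference between MCF7PR and MCF7 0 and that between BT549 and MB231 1, with fewer libraries to estimate the spread. RLE size factors gave 10 for the difference between MCF7PR and MCF7 and kept the other 26 counts within 1.5 times.

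Leaving out 1 library at a time gave 0 to 47 genes for MB231 COMB against ATRi, 0 to 293 for BT549 COMB, 2 to 137 for MCF7 COMB, 0 to 1 for MCF7 COMB against MYTi and 0 to 1 for MCF7PR COMB. The other 15 drug contrasts stayed at 0 to 0. The line comparisons gave 10072 to 11027 for MCF7PR and MCF7 and 9605 to 10183 for BT549 and MB231, and the differences 0 to 17 and 0 to 87. The months gave 79 to 3361 in BT549, 785 to 1753 in MCF7 and 106 to 935 in MCF7PR. Leaving out 1 replicate number in the paired fit, with 2 pairs left, gave for MB231 2 to 284, 2 to 75, 7 to 2459, 0 to 1746 and 0 to 2044 in the order above. BT549 gave 0 to 7, 0 to 1, 32 to 1486, 0 to 649 and 0 to 654, MCF7 5 to 36, 260 to 1289, 1313 to 2177, 40 to 1238 and 22 to 527, and MCF7PR 8 to 173, 563 to 2241, 2192 to 4170, 364 to 3332 and 2 to 143. The paired differences gave 1836 to 2944 and 78 to 1229.

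Of the list tests called at the preset correlation, 17 held and 167 were lost with an estimated correlation, 183 held with the replicate block with 30 added, and 181 held with RLE factors. The 17 are in MCF7 E2F targets and G2 and mitosis genes for COMB against DMSO, MYTi and ATRi, p53 targets against DMSO and MYTi and histones against MYTi. In MCF7PR they are immediate early genes for ATRi and for COMB against DMSO, MYTi and ATRi and interferon genes against MYTi, and in the vehicle comparison of MCF7PR and MCF7 the oestrogen, epithelial and mesenchymal lists. With an estimated correlation and the replicate block, 5 of the 17 were lost: the last 3 and the immediate early genes in MCF7PR for ATRi (adjusted p = 0.126) and for COMB against ATRi (adjusted p = 0.0759). Of the named genes called in the unpaired fit, 178 of 178 held with DESeq2 and 173 with RLE factors, and all 160 to which the replicate block applied. The unpaired fit called no gene for COMB against DMSO in MB231 or MCF7PR, nor for any single agent. Genes named there from the paired fit are therefore not among these, and were not checked in this way. With vehicle libraries of the other month added, 29 held and 25 did not. For COMB in BT549 these are PCDH18, KMO, CCR1, CFH, SEMA3D, CDK1, BBC3, NFKBIA and ZFP36, and in MCF7 CAPN8, PTPRE, LIF, PRIMA1, CITED4, TK1, RMI2, PKMYT1, PLK3, BBC3, TRIB3, ACAT2, CELSR2, EGR1, EGR3 and CDK1.

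Recovery of small changes was limited, and neither depth nor replicate number was varied. In simulated data with 50 genes changed 1.5-fold, the unpaired fit recovered 46% in MB231, 22% in BT549, 50% in MCF7 and 0% in MCF7PR, and the paired fit 84, 52, 70 and 76%. The simulated counts were drawn from the paired fit itself, with its replicate effects and its spread. The higher recovery of the paired fit was therefore built in, and does not show which fit suits the real libraries. The paired fit made 12, 5, 5 and 12 false calls, and the unpaired fit 0 in each.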

Other observations

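All tests of the 2 patterns in this part were chosen only after the results were seen, whereas the splits of libraries were not.

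MCF7PR and MCF7 vehicle libraries differed at 10448 of 16957 genes, and CDKN2A was at 0 counts in each MCF7 library and at 2.28 ± 0.78 CPM in May MCF7PR vehicle (SD, n = 3). Cells of MB231 or BT549 among the MCF7PR cultures would bring transcripts that are abundant in those lines and nearly absent from MCF7. Among genes under 1 CPM in MCF7 vehicle, the 50 highest in each of those lines were taken. In May MCF7PR vehicle they lay at medians of only 0.739% of the MB231 level and 0.212% of the BT549 level. An unrelated line in place of one derived from MCF7 would lack the high expression of the 17q23 and 20q13 regions, which are known to be gained in MCF7. The 34 genes of those regions that MCF7 expressed at 4 times or more both mesenchymal lines had a median ratio of 9.4 in MCF7PR to the higher of both lines (2.78 for 919 such genes elsewhere), with RPS6KB1 at 634 CPM in MCF7PR and 668 in MCF7. A large change of cell state within the line during selection may be considered, as a hypothesis. It would have to bring up CDKN2A from 0 counts in MCF7. It would also have to bring up EMC10, at 0 counts in MCF7 vehicle and 120 CPM in MCF7PR vehicle over both months. Whether MCF7 still carries these genes was not examined. A line that shares these gains stays open, since no genotype was examined.

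RB1 in MCF7PR vehicle libraries was at 4.73 ± 1.36 CPM in May and 29.4 ± 3.10 in April (SD, n = 3). MCF7 cells among the April cultures would need a share of 52.2%, but the 17 epithelial genes lay at a median of 4.29% of their April MCF7 level (highest 48.7%). A batch difference common to both lines would move RB1 in MCF7 too, where the log2 change from May to April was -0.103 (SE 0.161) against 2.737 in MCF7PR. A batch or culture difference limited to the MCF7PR libraries cannot be judged from MCF7. The ribosomal protein share of counts in MCF7PR was 6.04, 7.15 and 5.80% in May and 9.61, 11.28 and 8.43% in April. In MCF7 it was 5.76, 6.76 and 5.48% in May and 6.42, 6.37 and 5.99% in April. A change of the whole region would move the neighbours of RB1 alike, but the 13 expressed neighbours had a median log2 change of 0.781 (lowest -0.15, highest 1.19). Only MED4 (adjusted p = 0.0357) and EBPL (adjusted p = 0.0237) were called, which does not show that the others were unchanged. As a share of MCF7, the neighbours had a median of 46.1% in May and 62.6% in April, and RB1 8.54 and 56.6%. ITM2B went from 34.6 to 98.5% and MED4 from 46.1 to 99.2%. Only FNDC3A (103 to 80.4%) and KPNA3 (67.3 to 62.6%) went the other way. A change at RB1 itself could be the source, as a hypothesis. A partial change of the region, a mixture of MCF7PR subclones, and a culture or batch difference limited to MCF7PR stay open.

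For each of the 20 drug contrasts the 10 possible splits of 6 libraries are too few for a share under 0.05. In BT549 the real COMB against DMSO split called 220 genes and in MCF7 252, against 0 for the highest other split, so 1 of 10 splits reached the real count in each. In the other 18 the real count was 0 and so was the highest other, so all 10 splits reached it. The same limit holds for BT549 against MB231 in vehicle (10238 against 0) and for the months in BT549 (1929 against 0), MCF7 (1669 against 0) and MCF7PR (643 against 0), with 1 of 10 splits each. For MCF7PR against MCF7 in vehicle, 1 of 100 splits reached the real count of 10448 and the highest other called 0. This excludes only a random assignment of these libraries to the lines. The other splits mixed both lines within a group, which raises the spread, so low counts were bound to follow. They cannot tell a difference of the lines from one between the cultures used. Exchanging treatments within pairs gives only 4 arrangements, and in the paired fit of COMB against DMSO in MB231 the highest other arrangement called 422 genes against 916, and in BT549 COMB against ATRi 10 against 0.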
